A study of Mus musculus with 51 samples.

How the data were processed

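The series read chromatin in mouse male germ cells. The germ cells came from testes of animals 12 to 14 days old, and testis of 6-week-old animals was used for DMC1. ATAC-seq, in which a transposase inserts adapters into open DNA, and chromatin immunoprecipitation (ChIP) of histone marks after MNase digestion were done on enriched germ cells, per the labels. Of the 51 samples, those analysed here fall into ATAC of C57BL/6J (B6, n = 2), of the B6-Prdm9CAST-KI strain (KI, n = 2), of Hells wild type (wt, n = 2), of Hells conditional knockout (CKO, n = 3) and of (B6xCAST)F1 hybrids (n = 2). They also comprise H3K9ac of B6 (n = 3), KI (n = 2), Spo11/Spo11 (n = 1) and the F1 (n = 1), and H3K4me3 of Hells CKO (n = 3), Hells wt (n = 1), Spo11/+ (n = 1) and Spo11/Spo11 (n = 2). HELLS ChIP of KI testis (n = 2) came with 1 IgG control and 1 input. DMC1 ChIP of Hells heterozygotes (het) and Hells CKO came as 1 peak list per genotype, so that replicates could not be compared. The DBA/2J and Spo11 ATAC libraries were not analysed here.

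The deposited tables held raw counts of reads per region, whole numbers that were not normalised, for ATAC, H3K9ac, H3K4me3 and HELLS. For the F1 hybrids the deposited values were estimated counts per allele, with a B6 and a CAST value for each region, and they were rounded to whole numbers before testing. The deposited DMC1 lists gave positions without a score. A deposited segmentation assigned the genome to 11 chromatin states computed from C57BL/6J histone marks. The submitters' processing notes name CASAVA, BWA version 0.7.15, Bowtie version 0.12.9, MACS version 1.4.2 and the genome build mm10. Which tool made which file, and the read filters, are not given in the sources used here. Chromosome names and lengths were checked against mm10, and genes were taken from GENCODE M21. In the tables, 10 columns could not be matched to a sample or group by their names and were not used, and 56 duplicated regions were removed from the Hells ATAC table. Columns of the B6 and KI ATAC table name the strain but not the sample. Replicate numbers of B6 and KI ATAC therefore only name columns and may differ from the labelled replicates. Regions were not chosen alike in all tables: of the hotspot regions, 52.4% in the Hells ATAC table and 80.7% in the H3K4me3 table began and ended on a regular grid of fixed windows, against 0.189% and 4.12% of the other regions.

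Regions were sorted into classes. A hotspot overlapped a het DMC1 peak and no promoter. A promoter was 1000 bp either side of an annotated transcription start. Further classes were regions with a DMC1 peak in the CKO list alone and no promoter, regions with a HELLS peak, regions with none of these (other), and chromosome X. KI-higher and B6-higher regions were those that passed the KI against B6 test in the other assay: H3K9ac defined them for the B6 and KI ATAC libraries, and ATAC defined them for H3K9ac, H3K4me3 and the Hells ATAC libraries. For H3K4me3 and Hells ATAC the regions defined by H3K9ac were tested too, and are named as such where given. Overlap meant at least 1 bp. Shares of peaks are given with exact 95% binomial intervals, which cover counting error only, and against 100 circular shifts of a list along its chromosomes.

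Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The ATAC fits held the compared groups. The labels give library batches, which follow the strain in B6 and KI ATAC and H3K9ac and which Hells CKO and Hells wt ATAC libraries share in part, so that the batch served there as a block in an alternative fit. The H3K9ac and the H3K4me3 fits each held all their groups, so that a group of 1 library was assumed to vary like the others. In the F1, B6 and CAST counts were compared within each library, with the library as a block, in regions with at least 20 allele counts, and H3K9ac ratios used a pseudocount of 1. Classes and gene lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated correlation, and fry). Camera compares a class with the other regions, and fry tests it on its own. Unadjusted fry p values are given for the main classes where both compared groups had replicates. Overlaps were computed with GenomicRanges 1.54.1, figures with matplotlib 3.10.9 under Python 3.11.15, and DESeq2 1.42.0 served as an alternative test. No label says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

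The groups, tests, classes, alternatives and 10 gene lists with 206 genes were fixed before the data were examined, except where stated. Promoters with and without a CKO DMC1 peak were unplanned classes, and the class adjustments counted them. The splits of regions into equal bins, and of other regions by chromatin state, were not planned either. The lists were meiotic prophase and recombination, pachytene and spermatid, spermatogonia, Sertoli cell, Leydig cell, peritubular, stromal and endothelial, blood and macrophage, imprinted, HELLS and DNA methylation machinery, and housekeeping. Each gene was represented by the region on its promoter with the highest mean count. The text names, per comparison, up to 5 regions in each direction with the lowest p among those past the threshold with separate groups and a log2 fold change of at least 1 in size. It also names up to 3 listed promoters past the threshold per list, or else examples of highest count, the Hells and Prdm9 promoters, and the widest peaks of each list, of which those after the first are not reported here. Alternatives were DESeq2, RLE factors, library size alone, TMM from promoter regions, other filters, an adjusted p threshold of 0.01, other overlaps and promoter widths, and leaving out each library in turn.

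Total counts in regions ranged from 27952728 to 34572929 per library for B6 and KI ATAC and from 6416704 to 11352108 for Hells ATAC. They ranged from 13195275 to 30233934 for H3K9ac and from 13321006 to 42007820 for H3K4me3. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom from 1.64 for HELLS to 25.4 for H3K9ac of B6 replicates 1 and 2. On simulated data with 100 regions changed at each size, the test recovered 95 of 4-fold and 47 of 2-fold changes for KI against B6 ATAC (81887 regions), and 79 and 15 for Hells ATAC (94983). It recovered 48 and 9 for KI against B6 H3K9ac (91881), 36 and 1 for Spo11/Spo11 against B6 H3K9ac (91890), 71 and 11 for Hells H3K4me3 (78952), 80 and 19 for Spo11 H3K4me3 (78957), and 50 and 17 for the F1 ATAC alleles (70252). Unchanged regions made up at most 5.13% of the calls. The simulation gave regions of like level the same spread and changed few regions, up or down at random. In the real KI against B6 H3K9ac data 12.3% of regions were called, 98.3% of them higher. The simulated shares may therefore not carry over to the real data.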

Results

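PRDM9 is a zinc-finger histone methyltransferase that binds recombination hotspots in meiotic prophase and marks the neighbouring nucleosomes with H3K4me3, and HELLS is a SNF2-family chromatin remodeller. The series asked which chromatin these proteins open. Germ cells of C57BL/6J mice (B6) were compared with those of B6-Prdm9CAST-KI mice (KI), which carry the CAST allele of Prdm9, whose zinc fingers bind other sequences, on the B6 background. Hells wild type (wt) was compared with a conditional knockout of Hells (CKO), and Spo11/Spo11 mutants, which lack the enzyme that makes meiotic DNA breaks, served to separate chromatin from breaks. DMC1, the recombinase loaded on broken ends, marked the breaks themselves. All coordinates are in mm10. Region levels are CPM, counts scaled to the library's total in regions after adjustment by its TMM factor. Class levels are the median CPM of the class in each library.

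Sites of the B6 allele were less open, and a separate set of sites was more open, in KI germ cells. ATAC signal at the 4064 hotspot regions, taken from DMC1 peaks of Hells heterozygotes (het) with B6 Prdm9, had a median log2 fold change of −0.94 (quartiles −1.50 and −0.18), and their median level was 2.25 ± 0.0948 CPM in KI (SD, n = 2) against 4.09 ± 0.675 CPM in B6 (n = 2). At the 6078 regions where H3K9ac was higher in KI, ATAC signal was 2.54 higher on the log2 scale, with 5184 regions higher. Of the 2591 regions with a HELLS peak in KI testis, 1317 rose and 0 fell. The median log2 fold change over all 2591 was 1.09 (quartiles −0.17 and 3.07), and their median level was 8.86 ± 0.0777 CPM in B6 and 27.4 ± 1.37 CPM in KI. Promoters moved little, with 190 of 17555 higher, 88 lower and a median of −0.15. Over all 81887 regions, 5847 were higher and 1856 lower in KI (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), and 11328 passed at an unadjusted p under 0.05. Hotspots made up 1744 of the lower and 132 of the higher regions.

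The regions with the lowest p among those higher in KI were intergenic on chromosome 19 (60375276 to 60376813, log2 fold change 4.73, SE 0.199), on chromosome 17 (93980544 to 93982451, 4.50), on chromosome 13 (118407702 to 118409767, 3.92) and on chromosome 1 (193649057 to 193651451, 3.94), and in a UTR of Bicd1 (chromosome 6, 149555852 to 149557330, 4.35). All but the chromosome 19 region held a HELLS peak. The chromosome 19 region stood at 42.7 ± 6.00 CPM in KI and 1.61 ± 0.0402 CPM in B6. Among those lower in KI, an intergenic region of chromosome 6 (145268955 to 145270732) fell by 3.59 on the log2 scale, from 54.7 ± 9.93 to 4.54 ± 0.187 CPM. The others lay at the Olfr801 promoter (chromosome 10, 129674057 to 129675947, −3.09), in an exon of Myt1 (chromosome 2, 181811074 to 181813091, −3.11), in an exon of Gm32856 (chromosome 8, 129269161 to 129271392, −3.61) and in an intron of Nrp1 (chromosome 8, 128372185 to 128374084, −3.16). All 5 held a het DMC1 peak. The adjusted p of the 10 regions lay between 2.8e-07 and 4.2e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg).

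Among the gene lists, 1 of 17 spermatogonial promoters was lower in KI, that of Uchl1 (chromosome 5, 66675109 to 66677364, a ubiquitin hydrolase of spermatogonia, log2 fold change −0.53, SE 0.150), and 1 of 25 imprinted promoters, that of Nnat (chromosome 2, 157561056 to 157562211, −0.60, SE 0.174). Their adjusted p values were 0.0452 and 0.0476 (edgeR quasi-likelihood test, Benjamini-Hochberg), and both calls were lost without KI replicate 1 (0.552 and 0.619) and without KI replicate 2 (0.906 and 0.7004). No other listed promoter passed, in any of the 10 lists, and adjusted over the list alone the count was 0 in every list. By camera with the preset correlation the meiotic (−0.14), imprinted (−0.18) and HELLS and DNA methylation (−0.23) lists were lower, each with an adjusted p of 0.0363. With an estimated correlation the adjusted p was 0.761 for all 3 lists. The medians of the other lists were −0.15 for spermatogonia, −0.07 for pachytene and spermatid, −0.05 for Sertoli cell, −0.01 for Leydig cell, −0.05 for peritubular, stromal and endothelial, −0.01 for blood and macrophage (1 promoter) and −0.14 for housekeeping. The Prdm9 promoter had a log2 fold change of −0.07 (SE 0.170) and that of Hells −0.33 (SE 0.157), which passed only without B6 replicate 2 (−0.35).

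The class shifts of ATAC signal were past the threshold by camera with the preset correlation, but with an estimated correlation the adjusted p was 0.173 for hotspots and 0.162 for HELLS regions, against 0.0403 for the KI-higher regions (limma camera, Benjamini-Hochberg). By fry the unadjusted p was 0.0413 for hotspots, 0.0130 for HELLS regions and 0.000835 for the KI-higher regions. The library batches in the labels followed the strain, so no value within a batch could be had, and the KI-higher regions were chosen from H3K9ac libraries of other batches. Without KI replicate 1, KI replicate 2, B6 replicate 1 or B6 replicate 2 the counts were 5439, 5490, 10370 and 8669 higher and 1060, 1231, 8439 and 7789 lower, and the count of lower hotspots ranged from 1023 without KI replicate 1 to 2519 without B6 replicate 2.

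**Figure D1:**
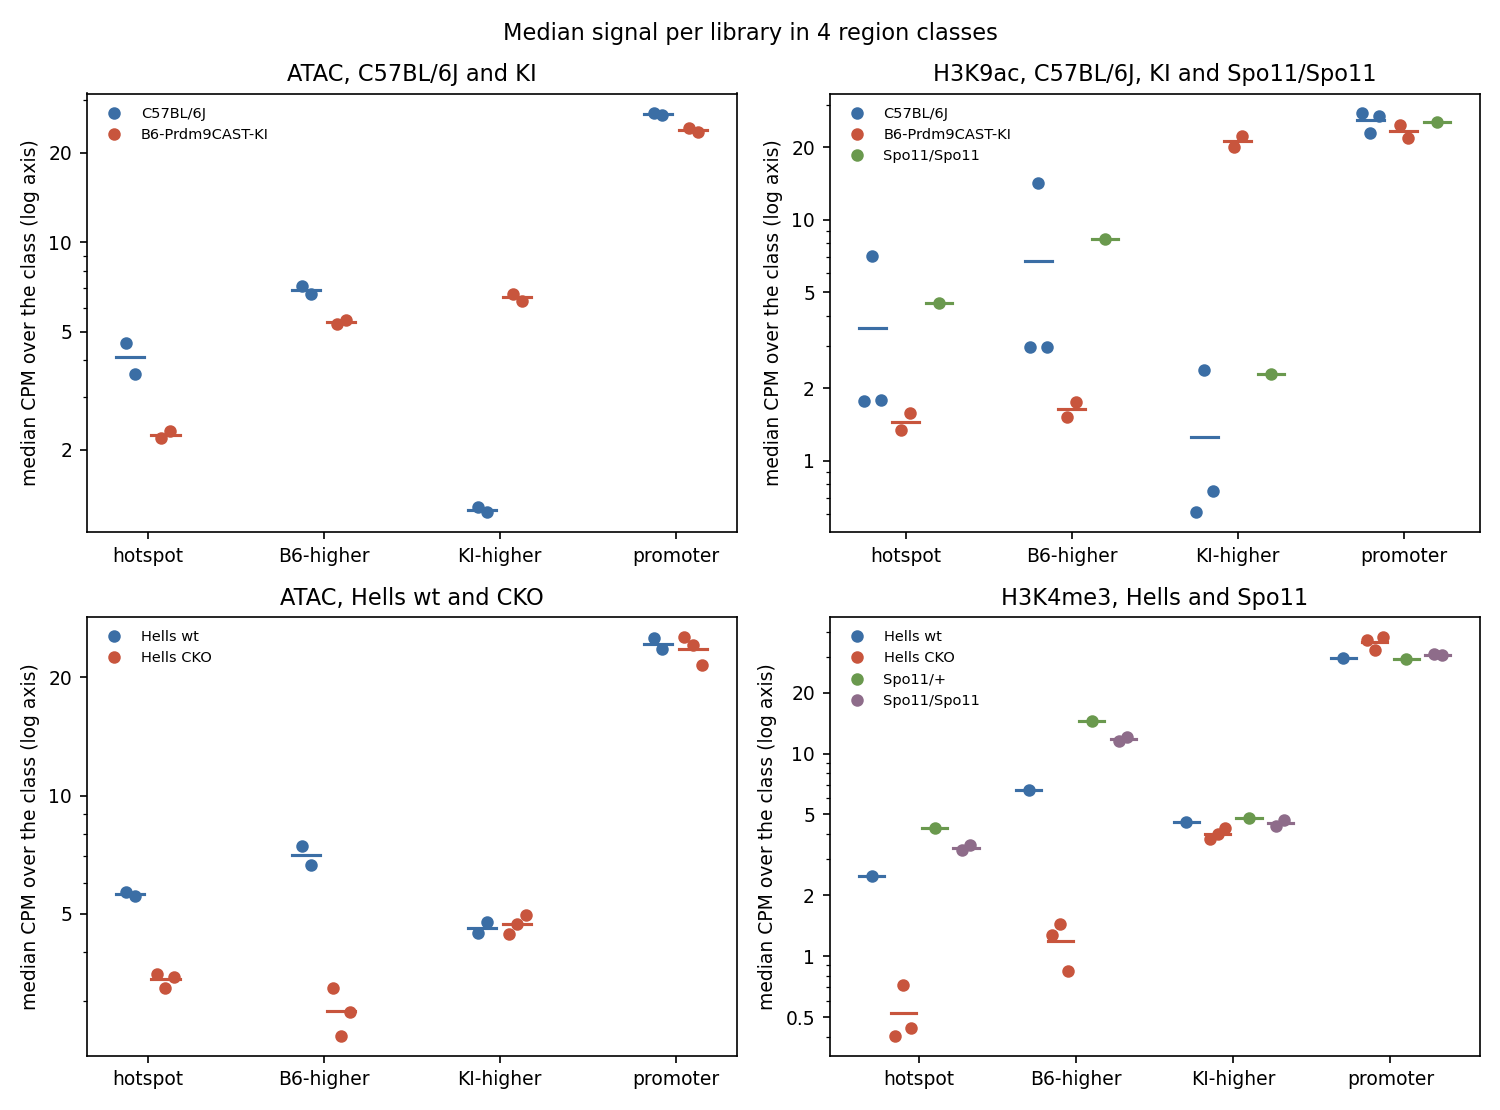
Median CPM (log axis) of each library in hotspots, B6-higher, KI-higher and promoter regions for ATAC of B6 and KI, H3K9ac, ATAC of Hells wt and CKO, and H3K4me3; points are libraries and bars are group means (the KI-higher and B6-higher regions of the first panel come from H3K9ac, those of the others from ATAC). Hotspot ATAC stood at 2.25 CPM in KI and 4.09 CPM in B6, and hotspot H3K4me3 at 0.522 CPM in Hells CKO and 2.48 CPM in Hells wt.

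H3K9ac, an acetylation mark of open chromatin, rose at the sites that opened in KI. At the 5596 regions with higher ATAC signal in KI, the mark had a median log2 fold change of 4.09, and 5086 of them rose, from 1.25 ± 0.99 CPM in B6 (SD, n = 3) to 21.2 ± 1.63 CPM in KI (n = 2). Of 2613 HELLS regions, 1301 rose and 0 fell. The regions with the lowest p lay on chromosome 8 (78497386 to 78499922, intergenic, 5.05), in an intron of Ramp1 (chromosome 1, 91214606 to 91218344, 3.55), on chromosome 13 (44289041 to 44290832, 4.93), on chromosome 11 (8172824 to 8174468, 5.39) and in an exon of Slc22a5 (chromosome 11, 53873818 to 53877040, 3.49), each with an adjusted p of 0.0045 (edgeR quasi-likelihood test, Benjamini-Hochberg). Lower regions with the lowest p included introns of Znrf1 (chromosome 8, 111571448 to 111575311, −1.43), Mboat2 (chromosome 12, 24928496 to 24929699, −1.77) and Stk24 (chromosome 14, 121365363 to 121367054, −1.46), and intergenic regions of chromosome 3 (90436453 to 90437805, −1.73) and chromosome 14 (54320871 to 54326016, −1.14). All but the Mboat2 region held a het DMC1 peak.

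At hotspots of the B6 allele and at KI-higher regions the H3K9ac libraries of B6 differed among themselves. The median level over 8034 hotspots was 1.77, 7.12 and 1.79 CPM in B6 replicates 1, 2 and 3, 1.34 and 1.57 CPM in KI replicates 1 and 2, and 4.51 CPM in the Spo11/Spo11 library. At the KI-higher regions it was 0.613, 2.39 and 0.750 CPM in B6 replicates 1, 2 and 3, 20.03 and 22.3 CPM in KI replicates 1 and 2, and 2.29 CPM in the Spo11/Spo11 library. B6 replicates 2 and 3 share a batch in the labels, and no batch held H3K9ac libraries of both B6 and KI, so no value within a batch could be had, while the KI-higher regions were chosen from ATAC libraries of other batches. The median log2 fold change between KI and B6 was −1.28 at hotspots, with 168 higher and 141 lower, and −1.99 at the 1819 B6-higher regions. Without B6 replicate 2 these medians were −0.32 and −0.87. With an estimated correlation the adjusted p was 0.599 for both classes and 0.304 for the KI-higher regions (limma camera, Benjamini-Hochberg). By fry the unadjusted p was 0.379 for hotspots, 0.226 for B6-higher regions and 0.00179 for the KI-higher regions.

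Over all 91909 H3K9ac regions, 11121 were higher and 191 lower in KI (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), and 21386 passed at an unadjusted p under 0.05. These counts moved when single libraries were left out, while the median of the KI-higher regions stayed between 3.75 and 4.88 over the 5 such fits: 0 higher and 0 lower passed without KI replicate 1 and again without KI replicate 2 (DESeq2 gave 13952 and 1552 on all libraries). Without B6 replicates 1, 2 and 3 in turn, 7031, 26360 and 1987 were higher and 46, 24586 and 0 lower, and the higher regions of the KI-higher class numbered 3900, 5505 and 1334. Among listed promoters only Prm2, a spermatid protamine (chromosome 16, 10790807 to 10791986, 2.91, SE 0.559, 6.54 ± 0.421 against 0.904 ± 0.608 CPM), and Vwf, an endothelial gene (chromosome 6, 125551879 to 125552872, 2.94, SE 0.661), rose, with adjusted p values of 0.0290 and 0.0468 (edgeR quasi-likelihood test, Benjamini-Hochberg). Both calls were lost without KI replicate 1 (0.142 and 0.220), KI replicate 2 (0.223 and 0.281) and B6 replicate 3 (0.118 and 0.160), and that of Vwf also without B6 replicate 1 (0.0771). The Hells (0.26) and Prdm9 (0.55) promoters did not pass with all libraries, and passed at 0.43 and 0.87 without B6 replicate 2. No list was called, with medians from −0.30 for imprinted and −0.28 for spermatogonia to 0.27 for meiotic promoters and an adjusted p of 0.971 with an estimated correlation in each list. With library size alone the median of all regions was −0.22, against −0.07 with TMM.

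ATAC and H3K9ac moved together at hotspots and at regions called in both assays, and by rank less so at promoters and other regions. Over 63409 regions measured in both assays, the log2 fold changes of KI against B6 had a Pearson r of 0.887 and a Spearman rho of 0.374, where regions are not independent replicates. Of 5237 regions called in both assays, 5236 had the same direction. Among hotspots Pearson r was 0.814.

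The Spo11/Spo11 mutant was compared with B6 to ask whether H3K9ac needs breaks. Hotspots had a median log2 fold change of 0.30, the KI-higher regions of 0.84 and the B6-higher regions of 0.31 in the mutant (n = 1, assumed to vary like the other groups), and with an estimated correlation the adjusted p of the hotspots was 0.760 and that of the KI-higher regions 0.647 (limma camera, Benjamini-Hochberg). The edgeR quasi-likelihood test called 0 regions higher and 0 lower, with 3616 at an unadjusted p under 0.05, and DESeq2 called 7 higher and 9 lower. Promoters of meiotic genes stood 0.41 higher, of HELLS and DNA methylation genes 0.26 higher, of housekeeping genes 0.20 higher and of peritubular, stromal and endothelial genes at −0.22 by camera with the preset correlation, but the adjusted p with an estimated correlation was 0.1997 for the first and 0.684 for the other 3. Without B6 replicate 2, 21202 regions were higher and 11639 lower, hotspots stood at 1.43, B6-higher regions at 1.49 and KI-higher regions at 1.66, and the Hells (0.67) and Prdm9 (0.64) promoters passed. Without B6 replicate 1 or 3 the hotspot median was −0.02 in both fits, that of B6-higher regions −0.03 in both and that of KI-higher regions 0.50 and 0.56, so that the direction at hotspots turned with the B6 library left out. The mutant library was the only one of its group, and no other H3K9ac library shared its batch.

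H3K4me3 at hotspots was lower in Hells CKO than in Hells wt. The median level of 12498 hotspots was 0.522 ± 0.174 CPM in Hells CKO (SD, n = 3) against 2.48 CPM in the Hells wt library and 4.29 CPM in the Spo11/+ library. The median log2 fold change was −2.28 (quartiles −2.66 and −1.78), and 8214 hotspots were lower and 1 higher. At the B6-higher regions 1775 of 1915 fell, with a median of −2.45, while the 419 KI-higher regions had a median of −0.08, with 50 lower and 0 higher. The 228 B6-higher regions defined by H3K9ac instead had a median of −1.23. Of the regions without a DMC1 peak, a HELLS peak or a promoter (other), 796 fell. Of these, 80.2% lay in chromatin state 7, against 3.95% of the other regions that were not called. Split by their level in the Spo11/+ library, hotspots had medians of −2.08, −2.25, −2.36 and −2.39 from the lowest to the highest of 4 equal bins, and 29.4%, 66.6%, 84.4% and 82.5% passed, a share that also depends on counts.

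The hotspots with the lowest p lay in introns of Gm14342 (chromosome 2, 180879803 to 180881598, −3.66) and Megf11 (chromosome 9, 64610603 to 64611998, −3.48), in exons of Sptbn5 (chromosome 2, 120065203 to 120067798, −2.86) and Prag1 (chromosome 8, 36139403 to 36140998, −3.62), and in a UTR of Prdm15 (chromosome 16, 97793403 to 97794998, −3.53). Each had an adjusted p of 3.3e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg). Regions that rose were led by an intergenic region of chromosome 5 (109906086 to 109907668, 1.77), an intergenic region of chromosome 14 (120761900 to 120764081, 1.15), an exon of Wif1 (chromosome 10, 121088829 to 121090444, 1.61) and introns of Abcc2 (chromosome 19, 43815245 to 43816611, 1.30) and Palld (chromosome 8, 61606116 to 61607582, 2.01). None of these 5 held a DMC1 peak.

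The Hells promoter (chromosome 19, 38929277 to 38932838) had 73.3 ± 15.9 CPM of H3K4me3 in Hells CKO and 54.8 CPM in Hells wt, and the labels do not say which part of the gene is removed, so that this checks nothing. Promoter regions as a class had a median of 0.27, with 9 of 18189 higher and 211 lower. By camera with the preset correlation promoters of Sertoli cell (0.59), housekeeping (0.41), HELLS and DNA methylation (0.42), spermatogonia (0.27), peritubular, stromal and endothelial (0.21), meiotic (0.14) and imprinted genes (0.13) were higher, and the pachytene and spermatid (0.18), Leydig cell (0.34) and blood and macrophage (0.51, 1 promoter) lists were not called. With an estimated correlation the adjusted p was 0.597 for the meiotic list and 0.428 for every other list. No single listed promoter passed, for example Ccnd2 (0.54) among spermatogonial, Wt1 (0.39) and Gata4 (0.48) among Sertoli cell and Zcwpw1 (0.26) among meiotic genes.

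Over all 78959 regions, 22 were higher and 9223 lower, so that 0.238% of the calls were higher (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), and 14277 passed at an unadjusted p under 0.05. With DESeq2 1042 were higher, 11.8% of the calls. Without Hells CKO replicates 1, 2 and 3 in turn, 454, 2544 and 6 regions were higher. The median of all regions was −0.02 with TMM, 0.09 with RLE factors, −0.17 with library size alone and −0.27 with TMM from promoters, and the KI-higher median turned to 0.03 with RLE factors. With an estimated correlation the adjusted p of hotspots and of B6-higher regions was 0.0783 (limma camera, Benjamini-Hochberg). Between the libraries of a shared batch the hotspot median was −1.70 and that of B6-higher regions −2.14. These are differences of log2 CPM with a prior count added, which draws changes at low counts toward 0. They are therefore not on the measure of the fits.

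Hotspots of the B6 allele were also less accessible in Hells CKO. The 3241 hotspots of the Hells ATAC table had a median log2 fold change of −0.33 (quartiles −1.21 and 0.00), or of −0.58 where the peak covered at least 50% of the region, and their median level was 3.41 ± 0.152 CPM in Hells CKO (n = 3) against 5.61 ± 0.0823 CPM in Hells wt (SD, n = 2). At the 1268 B6-higher regions the median was −1.34, from 7.06 ± 0.563 to 2.83 ± 0.396 CPM, and 355 fell. The 574 KI-higher regions had a median of 0.03, and the 1415 regions with a HELLS peak in KI testis of −0.12. Both lower classes held with an estimated correlation (adjusted p = 0.00847 for hotspots and for B6-higher regions, limma camera, Benjamini-Hochberg). By fry the unadjusted p was 0.00103 for hotspots and 0.00251 for B6-higher regions. The 195 B6-higher regions defined by H3K9ac instead had a median of −0.05, with 7 lower. Their adjusted p with an estimated correlation was 0.377 (limma camera, Benjamini-Hochberg). Split by their ATAC signal in B6, 2.65%, 9.35%, 16.0% and 27.1% of hotspots fell from the lowest to the highest of 4 equal bins, with medians of −0.29, −0.84, −0.86 and −0.56, so that the share called rose to the top bin while the median did not, and the 673 hotspots with no region in the B6 and KI table had a median of −0.0039.

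The lowest p belonged to intergenic regions of chromosome 2 (179249403 to 179252198, −2.32, SE 0.247) and chromosome 12 (26687203 to 26690998, −2.46), a region 1923 bp from the start of Serpina3i (chromosome 12, 104258403 to 104261198, −2.41), an intron of Ankfn1 (chromosome 11, 89610603 to 89613198, −2.26) and an intergenic region of chromosome 6 (145269003 to 145271798, −2.13). Each had an adjusted p of 0.00411 (edgeR quasi-likelihood test, Benjamini-Hochberg) and DMC1 peaks in both the het and the CKO list. The chromosome 6 region is the site that also led the regions lower in KI.

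Over 95033 regions, 363 were lower in Hells CKO and 0 higher by the edgeR quasi-likelihood test, 1468 passed at an unadjusted p under 0.05, and DESeq2 called 421 lower and 0 higher. Of the 363, 356 were hotspots. These counts moved when single libraries were left out, while the median stayed between −1.46 and −1.23 at B6-higher regions and between −0.44 and −0.35 at hotspots over the 5 such fits: 0 were lower without Hells CKO replicate 3 (1246 at an unadjusted p under 0.05), 132 without Hells wt replicate 1 and 626 without Hells CKO replicate 1, and 0 were lower with TMM from promoter regions (1299 at an unadjusted p under 0.05). Among hotspots and among B6-higher regions these counts were 0, 129 and 611, and 0, 131 and 598. With the library batch as a block, in which Hells CKO replicate 3 carries no weight, 1197 were lower and 14 higher. The Hells promoter had 35.9 ± 7.87 CPM in Hells CKO and 40.6 ± 7.73 CPM in Hells wt. No listed promoter passed. The meiotic list had a median of −0.26 (adjusted p = 8.6e-08 by camera with the preset correlation and adjusted p = 0.736 with an estimated correlation), and no other list was called.

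The ATAC and H3K4me3 changes in Hells CKO had a Pearson r of 0.565 and a Spearman rho of 0.0851 over 43633 regions, and of 0.617 and 0.614 over hotspots alone, where regions are not independent replicates. Of 359 regions called in both assays, all 359 were lower in both.

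H3K4me3 in Spo11/Spo11 against Spo11/+ asked whether the mark at hotspots depends on breaks. Hotspots had a median log2 fold change of −0.31 and stood at 3.43 ± 0.124 CPM in Spo11/Spo11 (SD, n = 2) against 4.29 CPM in Spo11/+ (n = 1), and B6-higher regions had a median of −0.29. With an estimated correlation the adjusted p of hotspots was 0.499 (limma camera, Benjamini-Hochberg). The edgeR quasi-likelihood test called 0 regions higher and 0 lower, with 159 at an unadjusted p under 0.05, and DESeq2 called 4 higher and 1 lower. Fitted without the Hells libraries, 16 were higher and 61 lower, and without Spo11/Spo11 replicate 1, 2 were higher. By camera with the preset correlation Sertoli cell promoters (0.23) and spermatogonial promoters (0.10) were higher, both with an adjusted p of 0.821 with an estimated correlation.

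Most DMC1 peaks of Hells CKO testis lay at other sites than those of Hells het testis, and most peaks in the CKO list alone lay at promoters. Of 15831 het peaks, 2079 (13.1%, 95% exact binomial interval 12.6 to 13.7) overlapped the CKO list, against 2.32% for shifted lists, and of 14692 CKO peaks 2008 (13.7%) overlapped the het list. A reciprocal overlap of 50% left 3.05% and 3.29% shared and the wider part of each list 6.43% and 6.78%, whereas on chromosome X 43.8% of het and 60.5% of CKO peaks were shared. Of the 13752 peaks in the het list alone, 545 (3.96%) overlapped a promoter, whereas 7774 of the 12684 peaks in the CKO list alone did (61.3%, 60.4 to 62.1), an odds ratio of 38.4 by Fisher's exact test, and 35.4% of the shared peaks did. H3K4me3 fell in Hells CKO at 52.1% of het peaks and at 2 of the peaks in the CKO list alone (0.0158%). Promoters with more H3K4me3 in Hells CKO held CKO DMC1 peaks more often, with 8.51%, 31.9%, 59.7% and 78.2% from the lowest to the highest of 4 equal bins, while het peaks stood at 8.64%, 5.59%, 5.59% and 8.01%.

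CKO DMC1 peaks lay at 32 of 36 promoters of meiotic genes, against 1 het peak, at Zcwpw1, a reader of PRDM9 marks, and at 13 of 15 housekeeping promoters. They lay at 16 of 28 imprinted, 10 of 17 HELLS and DNA methylation, 8 of 21 spermatogonial and 6 of 26 pachytene and spermatid promoters, and at 4 of 19 peritubular, stromal and endothelial, 2 of 12 Leydig cell, 2 of 20 Sertoli cell and 1 of 11 blood and macrophage promoters. Over all protein-coding genes the number was 8604 of 21924 (39.2%). The widest peaks of both lists were at the edge of the pseudoautosomal region of chromosome X in Mid1 (16463 bp, 169972096 to 169988558, in the het list and 103111 bp, 169867779 to 169970889, in the CKO list). The lists have no score, and nothing in them says how many animals stood behind a peak.

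**Figure D2:**
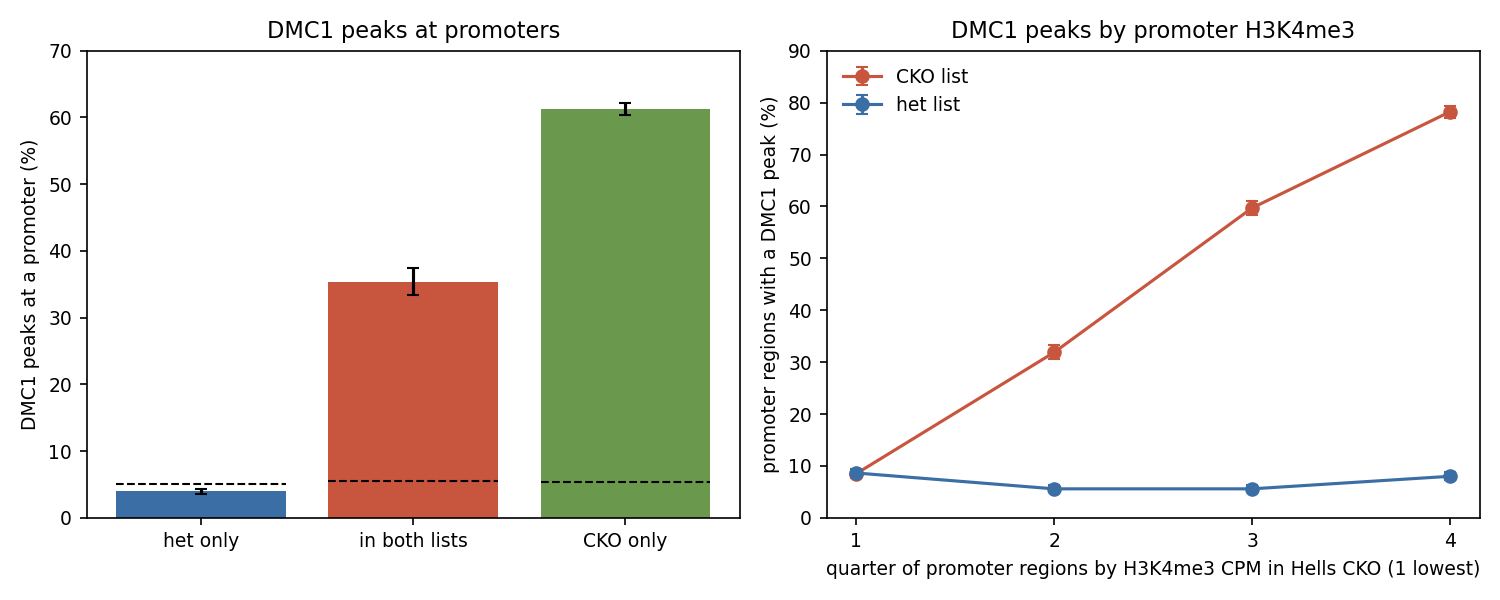
Left, percent of DMC1 peaks at a promoter for peaks in the het list alone (3.96%), in both lists (35.4%) and in the CKO list alone (61.3%), with 95% exact binomial intervals as bars and the mean of 100 shifted lists as dashed lines. Right, percent of promoter regions with a DMC1 peak, in 4 equal bins of H3K4me3 level in Hells CKO, which ran from 8.51% to 78.2% for the CKO list.

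HELLS in KI testis was bound at sites of the CAST allele and at promoters. Of 2675 HELLS peaks, 1308 (48.9%) overlapped KI-higher ATAC regions, against 0.347% for shifted peaks, and 0 overlapped B6-higher regions, which allows a share of up to 0.138% and is not told apart from the 0.104% of shifted peaks. Promoters took 47.9% of the peaks, het DMC1 peaks 3.21% and CKO DMC1 peaks 38.8%. The mean count of the 2 HELLS libraries, summed over peaks and not scaled for depth, was 7.70 times the IgG count and 4.38 times the input count at the 1307 peaks without a promoter that overlapped regions higher in KI in ATAC or H3K9ac, and 5.04 and 3.07 times at the 1226 promoter peaks outside such regions, while 55 peaks lay at both. HELLS peaks lay on 3.83%, 8.55%, 23.2% and 54.5% of KI-higher regions from the lowest to the highest of 4 equal bins of KI ATAC signal. Among the peaks with the highest counts were a Y peak by Gm47283 (90780398 to 90784220) with 682 and 644 HELLS counts but 276 of IgG and 471 of input, an exon of Scube2 (chromosome 7, 109844796 to 109847190) with 641 and 450 HELLS counts and 42 of IgG, and an intron of Trpm6 (chromosome 19, 18793532 to 18794682) with 355 and 205 and 7 of IgG. HELLS libraries held 185076 and 153260 counts in peaks and IgG 27308. HELLS was measured in KI alone, so binding at sites of the B6 allele was not analysed here.

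Hotspots of the B6 allele had a chromatin state of their own. State 7 covered 0.562% of the genome but 35.5% of the base pairs in het DMC1 peaks (63.2 times its genome share) and 85.2% of those in B6-higher regions (152 times). CKO DMC1 peaks lay in state 1 instead, with 54.6% of their base pairs (34.1 times its share), and HELLS peaks at promoters likewise (83.8%). Of the KI-higher regions, 45.6% of the base pairs lay in state 11, 1.04 times its share of the genome, in a segmentation built from B6 marks. States 6 (14.5%, 2.04 times), 3 (1.92 times) and 8 (1.86 times) exceeded their genome share there, and states 9 (0.439 times) and 10 (0.204 times) lay below it.

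(B6xCAST)F1 hybrids carry both Prdm9 alleles and both genomes. In them the KI-higher regions, taken as sites of the CAST allele, were more open on the B6 chromosome. These regions were chosen in mice with a B6 genome. That choice may by itself favour sites active on the B6 chromosome, and it was not excluded. KI-higher regions had a median log2 B6/CAST ratio of 0.40 in ATAC (5283 autosomal regions) and 0.56 in H3K9ac (1 library), and 1739 of them were higher on the B6 allele against 138 on the CAST allele. B6-higher regions had medians of −0.04 and −0.03, hotspots of −0.19 and −0.31, HELLS regions of 0.17 and 0.23, and promoters of 0.02 and 0.05. The KI-higher median exceeded the B6-higher median by 0.45 in ATAC (95% bootstrap interval 0.379 to 0.488) and by 0.59 in H3K9ac (0.524 to 0.663), each with a two-sided permutation p of 1e-05, the smallest that the resamples can give, over regions that are not independent replicates. Over 70654 regions the edgeR quasi-likelihood test called 5806 higher on B6 and 3908 on CAST, and on autosomes 4488 and 3897. Males carry 1 X chromosome, from the mother, and on chromosome X 1318 of 1399 regions were higher on B6, with 6.39% and 6.72% of ATAC counts and 2.16% of H3K9ac counts given to CAST.

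Regions with the lowest p on the B6 side were in an intron of Jarid2 (chromosome 13, 44868959 to 44870783, log2 ratio 4.63, a het DMC1 site), near Lama2 (chromosome 10, 27639165 to 27640228, 4.81) and on chromosome 8 (115653084 to 115655332, 5.44), and on chromosome X at Ap1s2 (163907470 to 163911075, 939 and 765 B6 counts against 1 and 1 CAST counts, a het DMC1 site). On the CAST side they were at Mipol1 (chromosome 12, 57406356 to 57407756, −4.47), Clstn2 (chromosome 9, 97593573 to 97594531, −4.54), Ppp1r12b (chromosome 1, 134903544 to 134904774, −5.65, a het DMC1 site), Cd44 (chromosome 2, 102829103 to 102829539, −7.28) and on chromosome 3 (29039352 to 29040297, −5.67, a het DMC1 site).

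**Figure D3:**
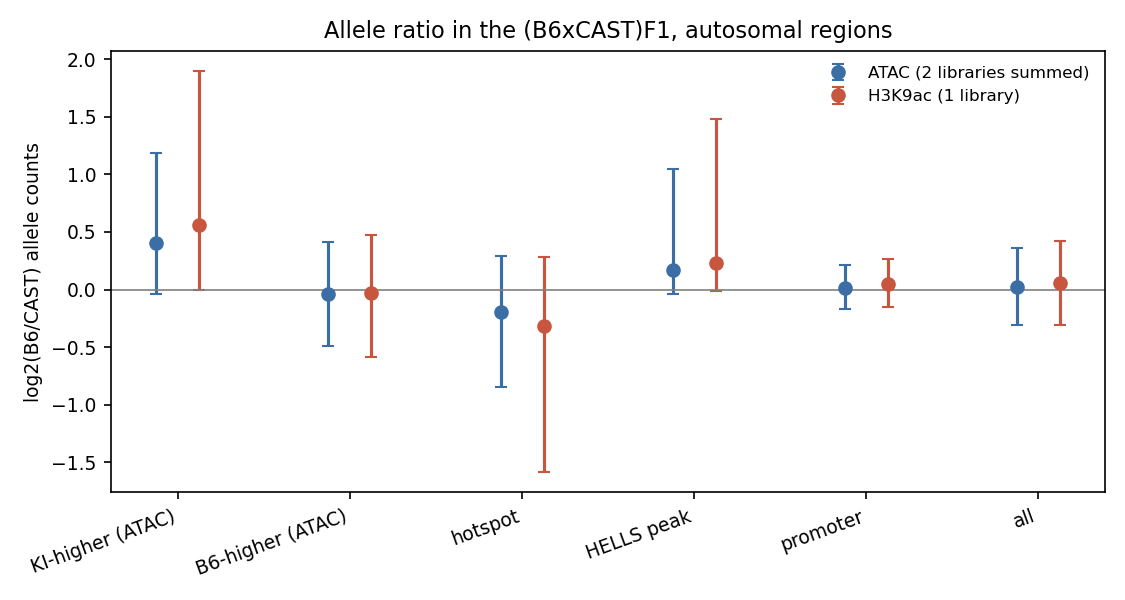
Log2 ratio of B6 to CAST allele counts in the F1 for autosomal regions of each class, with points at the median and bars from the lower to the upper quartile, for ATAC (libraries summed) and H3K9ac. The KI-higher regions stood at 0.40 and 0.56, and all regions at 0.02 and 0.05.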

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

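The fits with B6 replicate 2 as the lone B6 H3K9ac library, and the splits of the F1 and DMC1 results by autosomes and X, were chosen only after the results were seen. No named region or promoter turned its direction while past the threshold under any alternative that was run. Class medians were not tested again under the alternatives, and some turned direction. In Spo11/Spo11 H3K9ac, hotspots and B6-higher regions stood at 0.30 and 0.31 against all B6 libraries. The median log2 ratio of that library to B6 replicate 2 alone was −0.61 and −0.71. Of 1729 values for 166 named regions and promoters under the alternatives, 1638 stayed on the same side of the threshold, those never called included, 63 lost the call and 28 gained it. The cause of a change was not tested except where stated. The DMC1 lists have no score, so their wider part stood in for a stronger part, and HELLS peaks were ranked by their HELLS counts. Leaving out an F1 library leaves no residual degrees of freedom, and single libraries gave medians of 0.45 and 0.41 at KI-higher regions. The stricter adjusted p of 0.01 passes fewer regions by construction.

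For KI against B6 ATAC, leaving out libraries gave 5439 to 10370 higher and 1060 to 8439 lower regions and a KI-higher median of 2.47 to 2.58. The KI-higher median was 2.60 with library size alone and 2.67 with TMM from promoters, against 2.54, and the B6-higher median −0.23 and −0.16, against −0.29. At an adjusted p of 0.01, 1228 were lower.

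For Hells ATAC, leaving out libraries gave 0 to 1 higher and 0 to 626 lower regions, a hotspot median of −0.44 to −0.35 and a KI-higher median of −0.0075 to 0.14. With TMM from promoters 0 were lower and at an adjusted p of 0.01, 126. With the library batch as a replicate block 1197 were lower and 14 higher, in a fit where Hells CKO replicate 3, which has no wt partner in its batch, carries no weight. Hotspots that overlapped by at least 50% of the region had a median of −0.58.

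For KI against B6 H3K9ac, leaving out libraries gave 0 to 26360 higher and 0 to 24586 lower regions. DESeq2 called 1552 lower and library size alone 469, and at an adjusted p of 0.01, 2948 were higher and 4 lower. With B6 replicate 2 alone 7793 were lower. For Spo11/Spo11 against B6 H3K9ac, leaving out libraries gave 0 to 21202 higher and 0 to 11639 lower regions, B6 replicate 2 alone 379 and 1557, and DESeq2 7 and 9.

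For Hells H3K4me3, leaving out libraries gave 6 to 2544 higher regions. DESeq2 called 1042 higher, RLE factors 75, library size alone 12, TMM from promoters 5 and an adjusted p of 0.01, 1, with 6038 lower at the last. The KI-higher median was 0.026 with DESeq2, 0.027 with RLE factors, −0.24 with library size alone and −0.34 with TMM from promoters, which follow the shift of the median of all regions. The same-batch pair, on log2 CPM with a prior count added, gave a hotspot median of −1.70. For Spo11 H3K4me3, leaving out libraries gave 0 to 2 higher regions and a B6-higher median of −0.33 to −0.24. DESeq2 called 4 higher and 1 lower, and a fit of the Spo11 libraries alone 16 and 61.

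For DMC1, a reciprocal overlap of 50% left 3.05% of het and 3.29% of CKO peaks shared, the wider part of each list 6.43% and 6.78%, autosomes 10.9% and 11.2%, and chromosome X 43.8% and 60.5%. With promoters of 500 bp either side 2.80% of het-only and 59.6% of CKO-only peaks lay at promoters. Of HELLS peaks with the higher counts, 58.9% lay in KI-higher regions and 39.6% at promoters. By the state at the midpoint, state 7 held 67.5% of het DMC1 peaks and 92.0% of B6-higher regions, and state 1 held 63.5% of CKO DMC1 peaks. In the F1 no alternative moved a count by over 1.5 times. Of the ATAC, H3K9ac and H3K4me3 tables of the B6, KI, Hells and Spo11 groups, Hells ATAC had the lowest depth, but on simulated data the H3K9ac comparisons recovered the fewest regions changed 2-fold, 9 and 1 of 100, against 15 in Hells ATAC.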

Other observations

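In this part, the tests of promoter level and of a swapped genotype in the H3K9ac libraries, and of read placement and region choice in the F1, were chosen only after the results were seen. Hotspots with more H3K4me3 in Spo11/+ more often held DMC1 in Hells CKO: 1.25%, 3.01%, 7.87% and 30.05% held a CKO DMC1 peak from the lowest to the highest of 4 equal bins. Of het peaks that were also in the CKO list, 27.2% lay in B6-higher ATAC regions, against 11.35% of all het peaks. Peaks of the CKO list without a het peak or a promoter lay in states 1 (34.1%) and 2 (33.2%).

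H3K9ac at hotspots stood at 7.12 CPM in B6 replicate 2 and at 1.77 and 1.79 CPM in replicates 1 and 3, and replicate 2 was also the highest of the 3 at KI-higher regions (2.39 CPM). Weaker immunoprecipitation in replicates 1 and 3 was tested at promoters, whose median log2 ratio to replicate 2 was 0.0879 and 0.0493. Promoters were thus not lower, but TMM scaling of counts in regions, to which promoters add many, can hold this ratio near 0. The promoter test alone therefore cannot decide. Scaling moves the classes of a library nearly alike, so classes were also compared, after the values were seen. Other regions, with lower levels than promoters (3.40 against 23.0 CPM in replicate 2), stood at −0.133 and −0.112. Evenly weaker enrichment would raise low regions relative to promoters. These values argue against it in replicates 1 and 3, though every ratio rests on replicate 2. A swap with KI libraries is argued against by the KI-higher regions, which reached at most 0.750 CPM in replicates 1 and 3 against 20.03 and 22.3 CPM in KI. Fewer meiotic cells cannot be told apart from other causes: the gap of the meiotic list, −0.0999, lay just inside the limit of 0.1 set beforehand, but its interval of −0.32 to 0.07 is too wide to decide, a requirement added after the value was seen, and the pachytene and spermatid list was also lower in both (−0.15 and −0.14). The spermatogonial list stood 0.33 and 0.28 higher in replicates 1 and 3, but so did the Leydig cell (0.38 and 0.49), the peritubular, stromal and endothelial (0.36 and 0.20) and the Sertoli cell (0.24 and 0.13) lists, so that another mix of cells may contribute, as an untested hypothesis. The imprinted list, which is not a list of a cell type, was higher as well (0.40 and 0.31).

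In the F1, the KI-higher regions, taken as sites of the CAST allele, were tilted to the B6 chromosome. A general excess of B6 reads is argued against by the median of all autosomal regions, 0.0202 (0.0142 to 0.0247), a test that replaced one on hotspots, whose median was −0.19, after that value was seen. Choice of regions on a B6 genome stays open: the B6-higher regions stood at −0.0356 (−0.0794 to 0), but loss of binding at B6 sites could offset a tilt there. Hotspots also in the B6 and KI table had a median of 0 (−0.0456 to 0.0208) and the others of −0.58, but presence in a table of B6 genomes selects for activity on the B6 chromosome, so region choice and loss of binding at B6 sites cannot be told apart there. As an untested hypothesis, CAST sites may have lost binding on the chromosome that evolved with that allele.

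On chromosome X, 469 of 1072 het DMC1 peaks (43.8%, 40.8 to 46.8) were also in the CKO list, against 10.9% on autosomes, where single chromosomes ranged from 6.63% to 17.2%. Wider peaks and peaks at promoters are each argued against as the whole cause. The excess was 27.9 percentage points (25.03 to 30.6) within strata of width and 20.8 points (17.6 to 23.9) among peaks without a promoter. Kept H3K4me3 at X hotspots stays open. The median H3K4me3 change of X hotspots exceeded that of autosomal ones by 0.13 (0.0754 to 0.191), but a median can miss a mark kept at a minority of hotspots. The share called lower, which also depends on counts, went with this explanation, at 52.2% of X hotspots against 66.3% of autosomal ones. H3K4me3 was also read in younger animals than DMC1, and its change at the shared X peaks themselves was not tested. Width is only a stand-in for strength, which the lists do not give. No biological explanation was tested.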
